A study of Eurytemora affinis with 15 samples.

How the data were processed

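Whole adult males of Eurytemora affinis were kept at 15 psu and 15 °C before the exposure of 72 h, per the labels' protocols, and pools of 30 males were sequenced, with 3 pools in each of 5 groups. Libraries were made from 200 ng of total RNA with an mRNA sequencing kit, per the labels' protocols. The submitters' processing notes name STAR, Salmon, HTSeq 0.11.2 and DESeq2 without their roles; the genome build, the annotation and the strand setting are not given in the sources used here. The p-values measure the spread between the pools, which the labels call biological replicates. Reads shared between near-identical gene copies or overlapping genes could have been assigned to either copy, and this could not be checked.

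The values the authors deposited are a signal, gene read counts divided by 1 size factor per library, for 23728 genes, of which 23697 have a LOC identifier and 31 a tRNA identifier. 1754 genes are at 0 in every library. This was tested on the values: in each library all values above 0 (100%, tolerance 1e-06) were whole multiples of the value of 1 read, so that whole reads were recovered for every gene, and size factors recomputed with DESeq2's median of ratios from these reads equalled the deposited scaling. Each library had from 13.64 to 17.21 M reads in genes. The deposited table also holds a score per gene and library, Cook's distance, which measures how far 1 library moves a gene's fit. A DESeq2 fit with a term for group alone gave 100% of 329610 deposited distances within 1% of the value, against 0.564% with a replicate term added.

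The main test was limma 3.58.1 (R 4.3.3) on log2(value + 1), with 1 model over all 15 libraries with a term per group, an intensity trend and robust empirical Bayes moderation. Genes were kept with a value of at least 10 in at least 3 libraries, which left out 4807 genes and kept 18921. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 within a comparison, 2-sided, at any fold. A fold change on the log2(value + 1) scale understates the change of genes with few reads. The 10 comparisons were each exposed group and the mean of the 4 against Control, the concentrations within each site, the sites at each concentration, and the interaction. On the recovered reads, edgeR 4.0.16 (quasi-likelihood test, TMM scaling) and DESeq2 1.42.0 were run as alternatives. An adjusted p that DESeq2 left out was kept as missing.

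The groups, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, where no source pairs identifiers with names, at most 2 genes that rose and 2 that fell per comparison, those with the largest log2 fold change among called genes with the same sign of change in every pairing of libraries; where no gene passed, it took up to 3 with the smallest p. Genes named outside the rule are marked where they appear. The 31 gene lists fixed beforehand were patterns in product names, and 0 identifiers matched, so no test of gene lists was made and the annotated functions and genome positions of genes are not analysed here.

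Whole profiles were compared on log2(value + 1) by principal components and by a distance-based permutation test of group (adonis2 in vegan 2.7.1) with 99999 permutations. Co-varying gene sets came from average-linkage clustering of the 2000 genes with the largest SD, by correlation distance, with the tree divided at a height of 0.6 and sets of at least 100 genes kept. The sets were formed after the data were seen and on the same libraries, without the group labels. A set's level in a library was the median of its genes' log2 values, and groups were compared by an exact permutation test, whose smallest 2-sided p with 3 against 3 libraries is 0.1. Overlaps and correlations between comparisons with Control were set beside 100 simulations of unchanged groups that share the controls. Each simulation used the libraries' deviations from their group means, drawn with replacement and with random sign. Counting intervals are 95% exact intervals and cover counting error only, since the reads carry no molecular identifiers in the sources used here.

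Replicates were compared before averaging. Spearman correlations within groups were 0.940 to 0.991, and the read counts of all pairs differed by more than sampling noise, with a chi-square per degree of freedom of at least 9.80, so every library was counted once. The labels number the replicates 1 to 3 in each group, and whether the numbers pair the pools was checked by the correlation of deviations from the group means. All 3 same-number correlations were above 0.1 for Control with Tancarville 2500 mg/L (0.186, 0.167 and 0.428) and for Fatouville 350 mg/L with Tancarville 350 mg/L (0.103, 0.316 and 0.359), and for none of the other 8 pairs of groups. All 3 were negative for other pairs, among them Fatouville 2500 mg/L with Tancarville 2500 mg/L (-0.367, -0.321 and -0.406). For Tancarville 350 mg/L with Tancarville 2500 mg/L they were -0.531, -0.127 and -0.436. The positive correlations therefore do not establish a pairing. The labels do not say that a number marks a shared batch or day.

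The steps were tested on simulated data, with counts drawn from the real genes' means for Fatouville 2500 mg/L against Control and 200 genes changed. Limma recovered 71% of 2-fold and 96% of 4-fold changes with 9 false calls among 18748 genes, edgeR 72% and 96% with 9 false calls among 18771 genes, and DESeq2 83% and 96% with 27 false calls among 18921 genes. Each gene was drawn independently, the changed genes had a mean above 50, and no simulated library stood apart. The real libraries hold co-varying genes and libraries that stood apart, so these rates need not carry over to them. Alternatives varied the scaling (TMM, quantile normalisation), the pseudocount (0.5 and 5), the filter (none, or a mean of at least 50), the fold threshold, the moderation, library weights, the libraries in the fit, a replicate block and each library left out in turn. Added after the data were seen were fits without 3 libraries that stood apart, without the genes of the co-varying sets, and with the replicate block in 2 groups alone. Other splits of the libraries were refitted, all 10 for 3 against 3 and 100 draws otherwise. Figures were drawn with matplotlib 3.10.9.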

Results

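RNA was sequenced from adult males of the estuarine calanoid copepod Eurytemora affinis collected in the Seine estuary and held for 72 h in water alone or in sediment elutriate, the water phase recovered after mixing sediment with water. Elutriates came from 2 sites, Fatouville and Tancarville, and each was used at 350 and 2500 mg/L. Together with the water control this gave 5 groups of 3 replicates, described in the labels as biological replicates, and each of the 15 libraries was made from a pool of 30 males. The comparisons ask whether elutriates of estuarine sediment alter gene expression in this copepod, and whether the response depends on concentration and site.

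The reads assigned to genes numbered 17.1, 16.5 and 15.9 M in Control 1, 2 and 3, and 15.9, 15.2 and 16.3 M in the Fatouville 350 mg/L libraries. They numbered 15.8, 14.2 and 13.96 M at Fatouville 2500 mg/L, 16.4, 15.65 and 16.1 M at Tancarville 350 mg/L, and 15.0, 13.6 and 17.2 M at Tancarville 2500 mg/L. The deepest library held 1.26 times the reads of the shallowest. Of 23728 genes, 18921 passed the filter on low values and were tested, and a tested gene had a median of 179 reads per library. Values are given as normalised read counts (mean ± SD), with log2 fold changes on the scale of log2(value + 1), and genes are named by identifier only because the sources used here do not pair the identifiers with gene names.

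The whole profiles differed between groups to a modest extent. Group membership accounted for 44.2% of the variance over the 15 libraries (distance-based permutation test, F = 1.98, permutation p = 0.026). The distances of libraries from their group centres did not differ detectably between groups (permutation p = 0.914). Part of the variance share of group arises without any group effect. Among pairs tested the share was 52.35% for Fatouville 2500 mg/L against Control (n = 3, exact permutation p = 0.1, the smallest possible). It was 49.4% between the Fatouville concentrations (exact permutation p = 0.1) and 31.2% between the sites at 2500 mg/L (exact permutation p = 0.2). It was 16.1% between the Tancarville concentrations (exact permutation p = 0.6) and 14.3% between the sites at 350 mg/L (exact permutation p = 0.9). The first principal component held 43.1% of the variance and the second 17.6%. All 3 Fatouville 2500 mg/L libraries lay at the positive end of the first component together with Tancarville 2500 mg/L replicate 3. Control 3 stood apart from Control 1 and 2 on the second component, at 76.1 against 8.84 and -1.18.

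**Figure D1:**
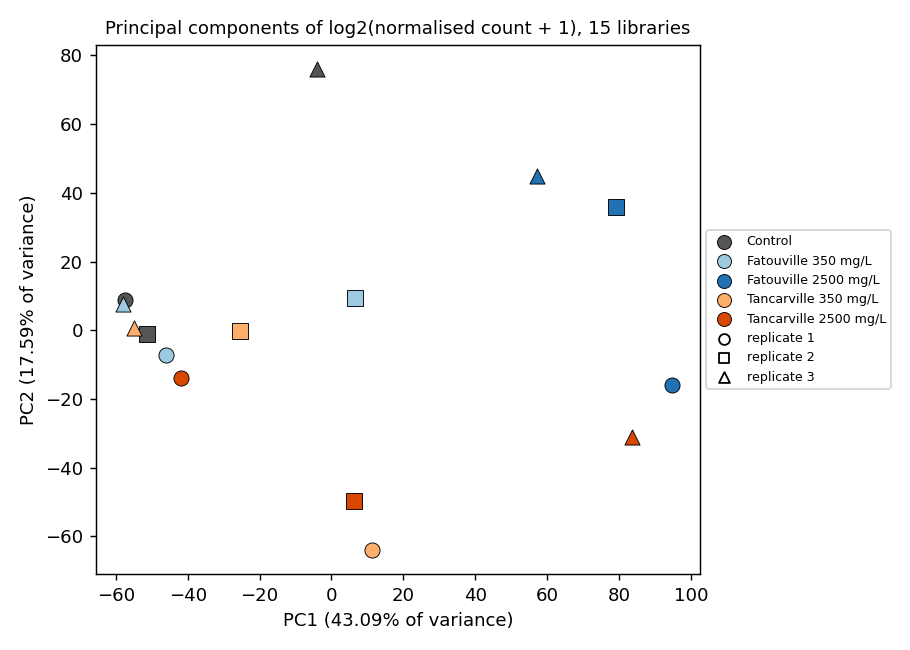
Principal component scores of the 15 libraries computed from log2(normalised count + 1), with the first component on the x axis (43.1% of variance) and the second on the y axis (17.6%). Colours mark the 5 groups and shapes the replicate number, and Control 3 sits at 76.1 on the second component, far from the other 2 controls.

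Some genes formed blocks whose levels varied together across pools, and the share of the whole variance that lay in them was not measured. Clustering the 2000 most variable genes without use of the group labels gave 4 co-varying sets of at least 100 genes, which held 1412 genes in all. Set 1 (670 genes) had a median normalised count of 10.4 to 13.4 in the 3 control libraries. It stood at 198, 61.5 and 50.4 in the Fatouville 2500 mg/L libraries and at 17.9, 85.2 and 166 in the Tancarville 2500 mg/L libraries. At 350 mg/L the same set was at 15.97, 30.1 and 11.6 for Fatouville and at 94.7, 19.9 and 11.8 for Tancarville, so that pools of 1 group differed by several fold. Set 2 (372 genes) was at 75.6, 154 and 123.1 in the Fatouville 2500 mg/L libraries, but also at 84.7 in Control 3 and 50.3 in Tancarville 2500 mg/L replicate 3, against 6.57 and 7.17 in Control 1 and 2. The genes of set 1 took from 0.177% to 3.83% of a library's reads and those of set 2 from 0.0617% to 3.44%.

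**Figure D2:**
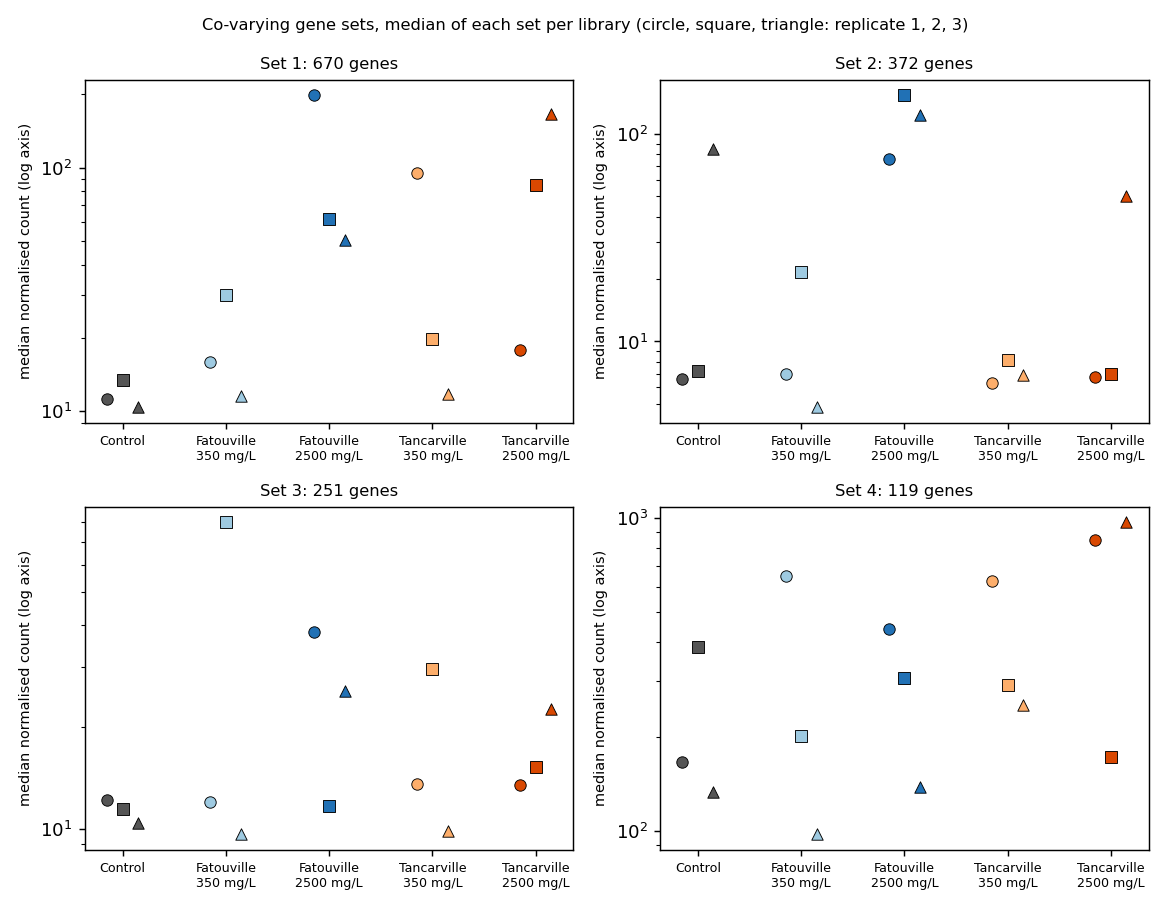
Median normalised count of the genes of each co-varying set (y axis, log scale) in each of the 15 libraries, arranged by group on the x axis, with circle, square and triangle for replicates 1, 2 and 3. Set 1 lies between 10.4 and 13.4 in the controls and between 50.4 and 198 at Fatouville 2500 mg/L, and set 2 is at 84.7 in Control 3 against 6.57 and 7.17 in the other controls.

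The higher concentration of Fatouville elutriate was compared with water alone. Among the genes called changed, the largest fall was that of LOC111712699, from 3275 ± 205 to 564 ± 115 normalised counts (SD, n = 3 per group), a log2 fold change of -2.55 (SE 0.27, limma adjusted p = 0.00442). The smallest p belonged to LOC111712470, named after its values were seen, which fell from 1458 ± 109.5 to 555 ± 64.6 (log2 fold change -1.39, SE 0.14, limma adjusted p = 0.000632). LOC111717563 also fell, from 337 ± 37.3 to 80.7 ± 24.8 (log2 fold change -2.09, SE 0.34, limma adjusted p = 0.032), a call lost in 6 of 21 alternatives (limma adjusted p up to 0.169). Among genes that rose, LOC111698906 went from 137 ± 29.2 to 275 ± 53.7 (log2 fold change 1.00, SE 0.19, limma adjusted p = 0.0451), a call lost in 8 of 21 alternatives (limma adjusted p up to 0.192). LOC111697735, a gene of co-varying set 2, had 104 reads over the 3 libraries of this group, where it ranged from 13.8 to 51.3 normalised counts, against 1 read in the controls and 1 in the other 9 libraries. Its ratio to the controls was 112 (95% counting interval 19.7 to 4470), with a log2 fold change of 4.66 (SE 0.87, limma adjusted p = 0.043). That call was lost with a pseudocount of 0.5 (limma adjusted p = 0.0568) and with the replicate block (0.0688). It was also lost without Control 1 or 2 (0.169 and 0.152). The adjusted p ranged from 0.00134 to 0.169 over 15 alternatives, and DESeq2 gave the gene no adjusted p. Only the 3 libraries of this group brought the gene past the filter of 10 in at least 3 libraries. The gene was therefore not tested with any of them left out, with a mean filter of 50 or without the set genes. Whether its call depends on 1 exposed library could not be checked.

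In all, 36 genes changed between Fatouville 2500 mg/L and Control by limma, 12 higher and 24 lower. Apart from LOC111697735, the genes that rose did so by 0.51 to 1.00 on the log2 scale, and those that fell had log2 fold changes of -0.46 to -2.55. Larger but more variable differences lay beside these calls. There were 1198 genes at least 2-fold higher in the exposed group and 111 at least 2-fold lower, and 1088 of the 1198 belonged to the co-varying sets. The sets were drawn from the most variable genes of these same libraries. Shares of 2-fold genes in the sets therefore follow in part from that selection, here and in the comparisons below. Of the 670 genes of set 1, 615 were at least 2-fold higher, and the set's median log2 level was 6.43 ± 1.06 against 3.66 ± 0.17 (SD, n = 3, 2-sided exact permutation p = 0.1, the smallest that 3 against 3 allows, and 0.533 after Benjamini-Hochberg adjustment over 32 set tests). For set 2, 332 of 372 genes were at least 2-fold higher, with medians of 6.83 ± 0.52 and 4.12 ± 1.99 (n = 3, exact permutation p = 0.2), the wide control SD coming with the level of Control 3. Only 1 of the 36 limma calls, LOC111697735, was in a set.

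At an unadjusted limma p under 0.05 there were 4303 genes in this comparison, 22.7% of those tested. This stood against 946 expected for independent genes and 3136 in the highest of the 9 other splits of the same 6 libraries, and the values of the 2 groups did not overlap in 25.3% of genes against 10% by chance. edgeR called 41 genes, 35 of them shared with limma, and DESeq2 called 1673 (909 higher and 764 lower), also with 35 shared. The limma count was 11, 2 and 860 without Control 1, 2 and 3, and 566, 15 and 3 without Fatouville 2500 mg/L replicate 1, 2 and 3, while quantile normalisation gave 98 higher and 453 lower genes in place of 12 and 24. A fit of these 6 libraries alone turned the balance, with 31 higher and 19 lower genes, 14 of them among the 36. LOC111712699 and LOC111712470 passed the threshold in each of the 21 alternatives tried, with log2 fold changes of -2.68 to -2.38 and -1.49 to -1.31.

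The lower Fatouville concentration gave no gene past the adjusted threshold against Control. The 3 genes with the smallest limma p all had lower values after exposure, and none passed by limma. LOC111712470 was at 819.5 ± 113 normalised counts against 1458 ± 109.5 in Control (log2 fold change -0.84, SE 0.14, limma adjusted p = 0.38). LOC111712699 was at 1123 ± 322 against 3275 ± 205, and LOC111712343 at 429 ± 75.9 against 793 ± 121 (log2 fold changes -1.59 and -0.89, limma adjusted p = 0.405 for both). At an unadjusted p under 0.05 limma gave 866 genes against 946 expected for independent genes and up to 1239 in other splits of the 6 libraries, edgeR called 0 genes and DESeq2 called 9, of which 2 were higher and 7 lower. The 7 included LOC111712470, LOC111712699 and LOC111712343, with DESeq2 adjusted p of 8.55e-05, 2.99e-06 and 0.00213. Set 1 had a median log2 level of 4.23 ± 0.67 against 3.66 ± 0.17 in Control (n = 3, exact permutation p = 0.2), with replicate 2 the highest of the exposed libraries. Set 3 was at 79.98 normalised counts in that same library and at 12.0 and 9.65 in the other 2.

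For the lower Tancarville concentration 3 genes changed against Control. LOC111712699 fell to 574 ± 17.9 normalised counts (log2 fold change -2.51, SE 0.27, limma adjusted p = 0.00765), close to its level at the higher Fatouville concentration. LOC111712470 fell from 1458 ± 109.5 to 683 ± 65.4 (log2 fold change -1.10, SE 0.14, limma adjusted p = 0.00765). LOC111708389 rose from 549 ± 30.4 to 889 ± 76.6 (log2 fold change 0.69, SE 0.10, limma adjusted p = 0.0236). There were 728 genes at an unadjusted limma p under 0.05 against 946 expected for independent genes and up to 929 in other splits of the 6 libraries. edgeR called the same 3 genes and DESeq2 called 20, the 3 among them. Of the 670 genes of set 1, 356 were at least 2-fold higher, with a median log2 level of 4.88 ± 1.51 (n = 3, exact permutation p = 0.2), carried by replicate 1. No gene passed when any 1 of the 6 libraries was left out, or without the 3 libraries that stood apart from their groups (Control 3, Fatouville 350 mg/L replicate 2 and Tancarville 2500 mg/L replicate 3). These 3, chosen after the data were seen, lay 82.7, 89.8 and 90.3 from their group centres. Tancarville 350 mg/L replicate 1, at 76.2, was kept, so the cut between them was a choice. The log2 fold changes in the fits with libraries left out lay at -2.56 to -2.47 for LOC111712699, -1.16 to -1.01 for LOC111712470 and 0.62 to 0.73 for LOC111708389. Over all 21 alternatives the call was lost in 7 for LOC111712699, 9 for LOC111712470 and 11 for LOC111708389.

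At the higher Tancarville concentration 4 genes changed against Control. LOC111712699 fell to 848 ± 357 normalised counts (log2 fold change -2.02, SE 0.27, limma adjusted p = 0.0289) and LOC111712343 fell from 793 ± 121 to 347 ± 60.9 (log2 fold change -1.19, SE 0.16, limma adjusted p = 0.0207). LOC111708389 rose to 872 ± 84.2 (log2 fold change 0.66, SE 0.10, limma adjusted p = 0.0289). The fourth gene, named after its values were seen, was LOC111712470, which fell to 663 ± 109 (log2 fold change -1.15, SE 0.14, limma adjusted p = 0.00857). Of the 855 genes at least 2-fold higher, 595 belonged to set 1, which had a median log2 level of 6.02 ± 1.61 against 3.66 ± 0.17 (n = 3, exact permutation p = 0.1, the smallest possible, and 0.533 after adjustment over 32 tests). Set 4 (119 genes) had 78 genes at least 2-fold higher, with medians of 9.03 ± 1.39 and 7.68 ± 0.81 (n = 3, exact permutation p = 0.2).

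An unadjusted limma p under 0.05 was reached by 1506 genes between Tancarville 2500 mg/L and Control, 7.96% of those tested, against 946 expected for independent genes and at most 1084 in another split of the 6 libraries. edgeR called 3 genes, all among the 4, and DESeq2 called 236 (215 higher and 21 lower), of which 170 were in the co-varying sets. The same-number deviations of these 2 groups all correlated above 0.1, which does not establish a pairing. With the replicate block limma called 3 genes, 2 of them among the 4, or 0 genes in a blocked fit of these 6 libraries alone. LOC111712699 and LOC111708389 no longer passed with the replicate block over all 15 libraries (limma adjusted p = 0.123 for both). Limma called 2, 0 and 0 genes without Control 1, 2 and 3, 3, 0 and 1 without replicates 1, 2 and 3 of the exposed group, and 0 without the 3 libraries that stood apart, and quantile normalisation gave 0 higher and 3 lower genes in place of 1 and 3.

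Averaged over the 4 exposed groups, 6 genes changed against Control, 1 higher and 5 lower. LOC111712699 fell (log2 fold change -2.17, SE 0.21, limma adjusted p = 0.00201), as did LOC111717563 (-1.89, SE 0.27, limma adjusted p = 0.0244), and LOC111708389 rose (0.54, SE 0.08, limma adjusted p = 0.0225). The other 3 that fell, named after their values were seen, were LOC111712470 (-1.12), LOC111712343 (-1.08) and LOC111696545 (-0.64), with limma adjusted p of 0.00052, 0.00269 and 0.0244. LOC111712699 ranged from 3044 to 3434 normalised counts in the controls and from 439 to 1371 in the 12 exposed libraries, and LOC111708389 from 515 to 574 and from 600.3 to 977. LOC111712470 was at 1336 to 1549 in the controls and 489 to 892 after exposure, and LOC111712343 at 684 to 924 and 299 to 493.

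**Figure D3:**
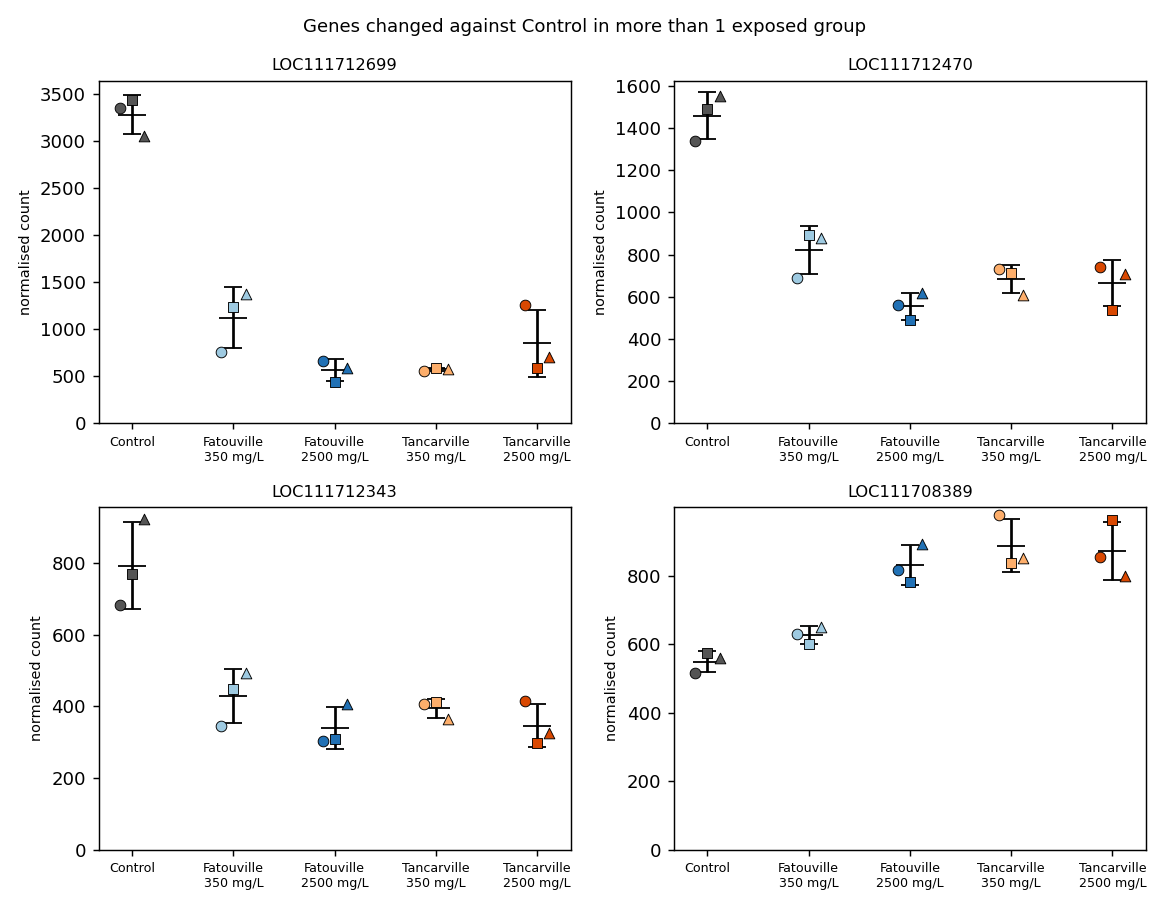
Normalised counts (y axis, linear from 0) of LOC111712699, LOC111712470, LOC111712343 and LOC111708389 in each library by group (x axis), with horizontal lines at the group mean and bars of 1 SD, n = 3. All 12 exposed libraries lie below the lowest control for the first 3 genes and above the highest control for LOC111708389. Over all tested genes 59 lie below and 71 above in this way, and the genes shown were chosen from calls on the same values.

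edgeR called 6 genes for the averaged comparison, the same 6, and DESeq2 called 146 (112 higher and 34 lower) including them, while 1329 genes had an unadjusted limma p under 0.05. The limma count was 3 with the replicate block and 1 without the 3 libraries that stood apart. It was 3 without Control 2 and 2 without Control 3.

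The changed genes recurred between exposures. By limma without the replicate block, Fatouville 2500 mg/L and Tancarville 2500 mg/L shared 3 genes that fell, each of them shared 2 with Tancarville 350 mg/L, and LOC111708389 rose in all 3 groups. With the block, LOC111712699 and LOC111708389 lost their calls at Tancarville 2500 mg/L (limma adjusted p = 0.123 for both), while LOC111712470 and LOC111712343 still passed (0.0374 and 0.0425). None of the 4 passed in the blocked fit of those 6 libraries alone (0.144 to 0.276). The rise of LOC111708389 lost its call in 8 of 21 alternatives at Fatouville 2500 mg/L, 11 at Tancarville 350 mg/L and 12 at Tancarville 2500 mg/L. Independent lists of these sizes would share at most 0.00381 genes that fell and 0.000634 that rose, and simulated unchanged groups set against the same controls shared on average 0.26 and 0.03. The simulated lists were not matched in size to the real ones. A simulated comparison had a median of 0 called genes and at most 4675, so these averages are no yardstick for the genes shared here. Over all genes the log2 fold changes correlated at 0.751 between the 2 Tancarville concentrations, at 0.675 between the 2 groups at 2500 mg/L and at 0.645 between the 2 groups at 350 mg/L, and at 0.245 between the 2 Fatouville concentrations. Simulated unchanged groups gave a median correlation of 0.527 (central 95% of draws -0.291 to 0.88), and all of these values lay inside. Each draw took whole libraries with replacement, so that 1 library could stand in several groups. The draws therefore do not show what shared controls alone give. The covariance was 0.354 between the 2 groups at 2500 mg/L, above the central 95% of simulated values, -0.0377 to 0.26 (mean 0.092). It was 0.208 between the 2 Tancarville groups and 0.12 or less for Fatouville 350 mg/L with any other group. It was 0.129 for Fatouville 2500 mg/L with Tancarville 350 mg/L, and these values lay inside that interval. Since the draws reused libraries, the interval does not decide whether a response was shared. With 3 controls the controls could not be divided into 2 parts of at least 2, and part of the overlap may come from the shared libraries. Genes are not independent replicates in these correlations.

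The effect of concentration was compared within each site. Between the Fatouville concentrations 1 gene changed, LOC111710162, which rose from 965 ± 62.1 to 2244 ± 322 normalised counts (log2 fold change 1.21, SE 0.17, limma adjusted p = 0.0441), and it was at 1171 ± 285 in Control. Set 2 had 352 of 372 genes at least 2-fold higher at 2500 mg/L (median log2 level 6.83 ± 0.52 against 3.35 ± 1.03) and set 1 had 523 of 670 (6.43 ± 1.06 against 4.23 ± 0.67), each with an exact permutation p of 0.1 at n = 3 and 0.533 after adjustment. An unadjusted limma p under 0.05 was reached by 3755 genes (19.8%), against at most 2682 in another split of the 6 libraries, and DESeq2 called 1065 genes (848 higher and 217 lower), LOC111710162 included. edgeR called 0 genes, with an adjusted p of 0.0562 for LOC111710162. Leaving out Fatouville 2500 mg/L replicate 1 gave 1103 genes by limma, and leaving out its replicate 3 or any replicate at 350 mg/L gave 0.

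Between the Tancarville concentrations no gene changed by limma. The gene with the smallest p, LOC111705609, had 397 ± 22.8 normalised counts at 2500 mg/L and 272 ± 11.01 at 350 mg/L (log2 fold change 0.54, SE 0.12, limma adjusted p = 0.857). LOC111712699 was at 848 ± 357 and 574 ± 17.9, a difference that did not pass (log2 fold change 0.48, SE 0.27, limma adjusted p = 0.857). Set 1 was at a median log2 level of 6.02 ± 1.61 and 4.88 ± 1.51 (n = 3, exact permutation p = 0.5). At an unadjusted p under 0.05 limma gave 1086 genes against 946 expected for independent genes and up to 1145 in other splits of the 6 libraries, edgeR called 0 and DESeq2 called 3, all higher at 2500 mg/L.

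The sites were compared at each concentration. At 350 mg/L no gene changed by limma. LOC111697329 had the smallest p, with 423 ± 110.3 normalised counts for Fatouville and 765 ± 29.1 for Tancarville (log2 fold change -0.88, SE 0.16, limma adjusted p = 0.826). There were 880 genes at an unadjusted limma p under 0.05 against 946 expected for independent genes and up to 1524 in other splits of the 6 libraries, edgeR called 0 genes and DESeq2 called 5. The same-number deviations of these 2 groups all correlated above 0.1, which does not establish a pairing, and limma called 0 genes with the replicate block too. It called 1 gene without Fatouville 350 mg/L replicate 3.

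At 2500 mg/L no gene passed the adjusted limma threshold between the sites, although many genes had a small unadjusted p. LOC111710162 was at 2244 ± 322 normalised counts for Fatouville and 1056.5 ± 172 for Tancarville (log2 fold change 1.09, SE 0.17), LOC111702887 at 604 ± 62.3 and 368 ± 22.7 (0.71, SE 0.11), and LOC111701255 at 99.8 ± 3.85 and 189 ± 12.2 (-0.91, SE 0.15), each with a limma adjusted p of 0.0651. Set 2 had 350 of its 372 genes at least 2-fold higher for Fatouville, with a median log2 level of 6.83 ± 0.52 against 3.88 ± 1.56 (n = 3, exact permutation p = 0.1, the smallest possible, and 0.533 after adjustment). Set 1 was at similar levels of 6.43 ± 1.06 and 6.02 ± 1.61 (exact permutation p = 0.8). An unadjusted limma p under 0.05 was reached by 3717 genes (19.6%), against 946 expected for independent genes and at most 2173 in another split of the 6 libraries. edgeR called 0 genes and DESeq2 called 888 (583 higher and 305 lower for Fatouville). Without Fatouville 2500 mg/L replicate 1 limma called 997 genes, and without Tancarville 2500 mg/L replicate 3 it called 3.

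Whether the concentration effect differed between sites was tested as an interaction, and no gene passed by limma. The gene with the smallest p was LOC111705060, at 837 ± 114 and 578 ± 31.2 normalised counts for Fatouville at 2500 and 350 mg/L and at 539 ± 61.0 and 720.4 ± 47.1 for Tancarville (interaction 0.95 on the log2 scale, SE 0.18, limma adjusted p = 0.63). At an unadjusted p under 0.05 limma gave 1465 genes (7.74%) against 946 expected for independent genes, edgeR called 0 and DESeq2 called 1. Without the 3 libraries that stood apart limma called 172 genes. For 163 of them the change from 350 to 2500 mg/L was more positive for Fatouville than for Tancarville, which a fall at Tancarville can also give.

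**Figure D4:**
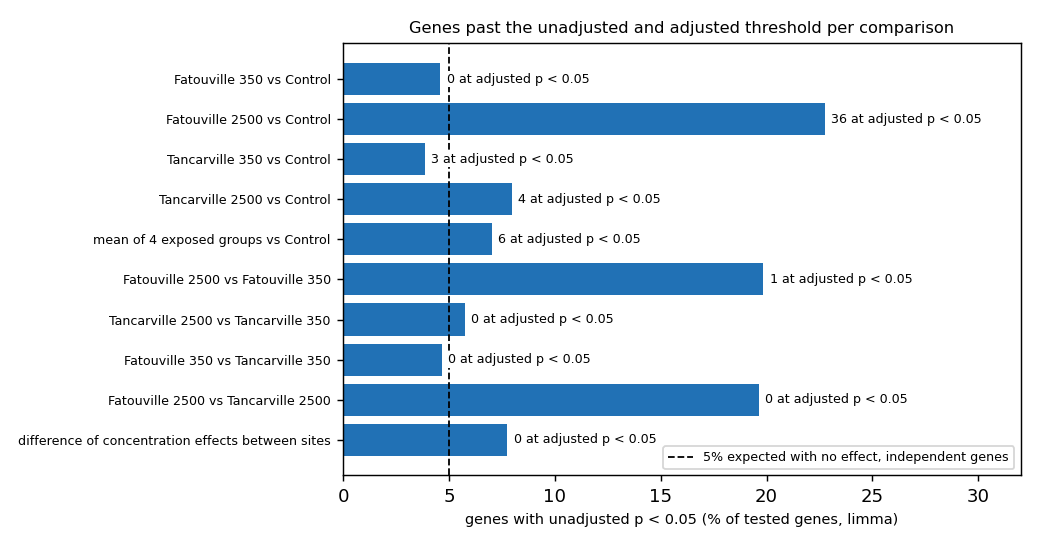
Share of the 18921 tested genes with an unadjusted limma p under 0.05 (x axis, percent) for each of the 10 comparisons (y axis), with the number of genes past the adjusted threshold written at each bar and a dashed line at the 5% expected with no effect for independent genes. The 3 comparisons that involve Fatouville 2500 mg/L against 1 other group reach 22.7%, 19.8% and 19.6%, and the others lie between 3.85% and 7.96%.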

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

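The tests of the Fatouville exposure as whole cause, of depth, of Control 3, of the set genes, of scaling, of the control vessels and of the 3 libraries that stood apart were chosen after the results were seen; the test of 1 fixed profile and the other splits were chosen before. The deposited Cook's distances, which enter no comparison, were above the highest control median of 0.0225 (Control 3) in 4 exposed libraries. The medians over genes were 0.0319 in Fatouville 350 mg/L replicate 2, 0.023 in Fatouville 350 mg/L replicate 3, 0.0316 in Fatouville 2500 mg/L replicate 1 and 0.0251 in Tancarville 2500 mg/L replicate 3. Single genes above the 5.64 limit numbered 22 in Fatouville 350 mg/L replicate 2, 20 in Control 3, 19 in Tancarville 2500 mg/L replicate 3, 7 and 2 in Tancarville 350 mg/L replicates 2 and 1, and 1 in Fatouville 2500 mg/L replicate 1.

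The 372 genes of set 2 were high in all Fatouville 2500 mg/L libraries and also in Control 3, Fatouville 350 mg/L replicate 2 and Tancarville 2500 mg/L replicate 3. Exposure to the Fatouville elutriate as the whole cause is argued against by Control 3, in which 62.4% of the genes (232 of 372) were at least 4-fold higher than in both other controls. Depth is argued against too, since the median ratio of Control 3 to the other controls was 7.89 while their read totals differed by a factor of 0.947. Another source of RNA with 1 fixed profile would keep the genes' excesses in 1 ratio between libraries, and the SD over genes of the log2 ratio had a median of 1.21 over 15 pairs, past the bound of 1 set beforehand, but fell to 0.865 and 0.809 for Control 3 with Fatouville 2500 mg/L replicates 2 and 3. Replicates of Fatouville 2500 mg/L differed among themselves by 0.928 to 1.02, so that bound does not separate such a source from the spread between pools, and it may remain, as may an untested difference in the state of the pools or an effect of the exposure on top of either.

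The number of genes changed between Fatouville 2500 mg/L and Control moved between 2 and 2400 with the setting. It was 860 without Control 3, against 11 and 2 without Control 1 and 2, which is consistent with Control 3 widening the spread, although leaving out Fatouville 2500 mg/L replicate 1 also gave 566. Leaving out the genes of the 4 sets gave 333, so that these genes may widen the moderated spread of the others, and both candidate explanations can hold together. Only 10 splits of the 6 libraries exist, too few for a share under 0.05. Of these, 2 gave as many genes as the real 36 by limma, the highest other with 282 placing Control 3 with Fatouville 2500 mg/L replicates 2 and 3, which points to a structure of the samples, and by DESeq2 1 split, the real one with 1673, gave as many, the highest other being the same split with 676.

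LOC111712699, LOC111712470 and LOC111712343 were below every control in all 12 exposed libraries, and they were chosen from calls on the same values. Over all tested genes 59 lay below in this way. When 3 libraries drawn at random stood in as controls, as many or more did so in 23 of 100 draws. The lack of overlap by itself therefore does not stand out. Scaling is argued against, since LOC111712699 kept a log2 fold change of -2.18 for the mean of the exposed groups under quantile normalisation. Without the 3 libraries that stood apart, the smallest fall of the 3 genes was -0.96 on the log2 scale. Since all 12 exposed libraries lay below every control, leaving libraries out could not reverse the direction. The fit therefore shows the size of the falls without those libraries and does not test them as a cause. In that smaller fit LOC111712470 alone still passed for the mean of the exposed groups (limma adjusted p = 0.106 for LOC111712699 and 0.0767 for LOC111712343). A property of the control vessels other than the absence of elutriate cannot be told apart from an effect of elutriate, because the design has 1 kind of control and the tools differ on whether the genes depend on concentration. The smallest limma adjusted p of the 3 genes between concentrations or sites was 0.0648, while DESeq2 gave 0.00544 for LOC111712699 and 0.00915 for LOC111712470 between the Fatouville concentrations, and a response to elutriate may be a part of the pattern, as a hypothesis that rests on the same 3 control pools throughout.

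For the other comparisons of 3 against 3 libraries the 10 splits were likewise too few for a share under 0.05. For Tancarville 350 mg/L and 2500 mg/L against Control 1 of 10 splits, the real one, gave as many genes (3 and 4, highest other 0 in both). Between the Fatouville concentrations 2 of 10 splits gave at least the 1 gene called, with 7 the highest other. Where the real count was 0, all 10 splits gave as many, with a highest other of 0 for Fatouville 350 mg/L against Control, 126 between the Tancarville concentrations, 0 between the sites at 350 mg/L and 8 between them at 2500 mg/L. For the mean of the exposed groups 5 of 100 splits gave at least the 6 genes called, the highest other giving 2034, so chance was not excluded and some splits followed a structure of the samples. For the interaction, with 0 genes called, 100 of 100 splits gave as many and the highest gave 539.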

How the results depend on the processing

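The fits without the 3 libraries that stood apart or without the set genes, and the block in 2 groups alone, were chosen after the data were seen. None of the 30 results tried for single named genes changed direction in their 670 alternative values. Most of these genes were named for a change of the same sign in every pairing of libraries or for a small p. Leaving out a library could therefore hardly reverse them, and the absence of reversals is no test of stability. Of the 456 alternative values for genes that passed, 329 kept their side of the threshold and 127 lost it. For Fatouville 2500 mg/L against Control, 36 genes became 8 with a log2 fold change of at least 1, 298 with a mean filter of 50, 551 under quantile normalisation, 11 without trend and robust moderation, 2400 with library weights, 1673 with DESeq2, 10 with the replicate block, 83 with the block in 2 groups, 1726 without the 3 libraries and 333 without the set genes; all 36 were among those under weights, quantile normalisation and without the 3 libraries. In 2 groups alone it gave 50, of which 14 were among the 36, and with the block in 2 groups 12 of the 83 were. More genes were higher than lower in 2 groups alone (31 and 19), with the block in 2 groups (72 and 11), with library weights (1357 and 1043), with DESeq2 (909 and 764), without the 3 libraries (907 and 819), without Control 3 (545 and 315) and without Fatouville 2500 mg/L replicate 1 (395 and 171), against 12 and 24 in the main test. For Tancarville 350 mg/L against Control, 3 genes became 1 without trend and robust moderation, 20 with DESeq2, 6 in 2 groups alone, 0 without the 3 libraries and 5 without the set genes. For Tancarville 2500 mg/L against Control, 4 genes became 0 without trend and robust moderation, 236 with DESeq2, 0 in 2 groups alone, with or without the block, and 0 without the 3 libraries. For the mean of the exposed groups, 6 genes became 3 without trend and robust moderation, 146 with DESeq2, 3 with the replicate block and 1 without the 3 libraries.

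Between the Fatouville concentrations 1 gene became 116 with a pseudocount of 5, 2 without a filter, 2 without trend and robust moderation, 1186 with library weights, 0 with edgeR, 1065 with DESeq2, 189 with the replicate block, 197 in 2 groups alone, 280 with the block in 2 groups, 683 without the 3 libraries and 110 without the set genes. Between the sites at 2500 mg/L 0 genes became 1 without a filter, 1 without trend and robust moderation, 1214 with library weights, 888 with DESeq2, 5 in 2 groups alone, 27 with the block in 2 groups, 881 without the 3 libraries and 177 without the set genes. DESeq2 gave 9 genes in place of 0 for Fatouville 350 mg/L against Control, 3 between the Tancarville concentrations, 5 between the sites at 350 mg/L and 1 for the interaction, which gave 172 without the 3 libraries. Apart from the smaller numbers of libraries or genes in some fits, the cause was not tested.

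With each library left out in turn, where a group of 2 is assumed to vary like the others, the counts ranged from 2 to 860 for Fatouville 2500 mg/L, 0 to 0 for Fatouville 350 mg/L, 0 to 0 for Tancarville 350 mg/L and 0 to 3 for Tancarville 2500 mg/L against Control, and from 2 to 8 for the mean of the exposed groups. They ranged from 0 to 1103 between the Fatouville concentrations, 0 to 997 between the sites at 2500 mg/L, 0 to 1 between them at 350 mg/L, and were 0 between the Tancarville concentrations and for the interaction. The same-number deviations were not all above 0.1 in 8 of 10 pairs of groups, and a library correlated best with its own number in at most 2 of 3 cases. The replicate block changed no count by over 1.5 times other than those given. TMM scaling moved the median log2 fold change by at most 0.0216. The fit of 2 groups alone does not apply to the mean of the exposed groups or the interaction, and the tests of gene lists (camera with an estimated correlation, fry) were not run because 0 identifiers matched. Counting limits genes with few reads, such as LOC111697735, where 1 control read gives an interval of 19.7 to 4470.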

Other observations

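The 2 smaller co-varying sets varied between pools of the same group. Set 3 (251 genes) had a median normalised count of 79.98 in Fatouville 350 mg/L replicate 2, 38.0 and 25.5 in Fatouville 2500 mg/L replicates 1 and 3, 29.6 in Tancarville 350 mg/L replicate 2 and 22.6 in Tancarville 2500 mg/L replicate 3, and lay between 9.65 and 15.2 in the other 10 libraries. Its median log2 level was 4.14 ± 0.37 at Tancarville 2500 mg/L and 3.63 ± 0.11 in Control (SD, n = 3, exact permutation p = 0.1, the smallest possible, and 0.533 after adjustment over 32 tests), and 4.56 ± 0.83 at Fatouville 2500 mg/L (n = 3, exact permutation p = 0.2 against Control). Set 4 (119 genes) was abundant in every library, from 97.4 in Fatouville 350 mg/L replicate 3 to 968 in Tancarville 2500 mg/L replicate 3, and took up to 4.51% of the reads in Tancarville 2500 mg/L replicate 1. Its controls were at 165, 385 and 132.5 in replicates 1, 2 and 3. Control 3, in which set 2 was high, had LOC111712699 at 3044 normalised counts, below the 3348 and 3434 of Control 1 and 2 and above the 1371 of the highest exposed library.

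The most abundant gene in 14 of the 15 libraries was LOC111706020, with up to 1.58% of the reads (Control 1); in Tancarville 350 mg/L replicate 1 it was LOC111715465, with 0.958%. The tRNA identifiers had a mean value of at most 0.926 normalised counts. Over all genes, 59 had all 12 exposed libraries below all 3 controls and 71 had all 12 above, against 41.6 in each direction if genes were independent (0.22% of genes by chance). When 3 of the 15 libraries drawn at random stood in as controls, as many genes or more lay below in 23 of 100 draws and above in 10 of 100, with highest counts of 505 and 482, so neither number stands out from other choices of 3 libraries.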
